A study of Penicillium oxalicum with 9 samples.

How the data were processed

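The series holds 9 RNA sequencing libraries of Penicillium oxalicum mycelia, from 3 deletion strains with biological triplicates each. Per the labels, mycelia were grown in Vogel's medium at 30 °C and 200 rpm, moved from 2% glucose (22 h) to medium without carbon (2 h) and then to 2% cellulose (4 h), and extracted with RNAiso; libraries followed standard Illumina protocols. The submitters' processing notes name CASAVA 1.8. The aligner, the counting tool, the genome build and the gene models are not given in the sources used here.

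The deposited table lists 9786 genes by locus number, with coding length, a description, a KEGG orthologue entry and, for each library, 3 columns of values. The authors gave whole read counts, which their header calls unique reads, and the total in each header equals the sum of its column. The authors also gave RPKM, which equals the reads of a gene divided by its length in kilobases and by the M reads (reads in units of 1e+06) counted in genes of that library. The deposited coverage in percent of the gene length was not used. A dash in the deposited counts stands for no reads and was read as 0. Of the lengths, 99.97% are multiples of 3. The descriptions of 9397 genes read only hypothetical protein, and 3519 genes have an informative description or KEGG entry. The reference table of locus tags matched 0 of the locus numbers, so no gene has a position, and GC content could not be computed without sequence.

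Libraries held 6.49 to 7.76 M reads in genes, and the depth of each is the total of its count column. The precision of a single library at low counts is set by the 3 reads that a count of 0 allows. Where a strain had 0 reads in a gene, the bound on the fold uses 3 reads over the strain; with 1 read, the ratio is given with an exact 95% binomial interval. Both cover counting error only.

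Strains were taken from the sample titles, and the columns were matched to the samples by the codes in the sample descriptions. The design fixed before the data were examined foresaw limma on RPKM unless read counts were given, in which case edgeR on the counts takes its place; counts were given, so edgeR was used and limma is an alternative. Genes were kept by filterByExpr (8681 of 9786), libraries were scaled by TMM (factors of 1.20 to 1.24 in dPoflbC, 0.988 to 1.03 in dPoClrC, and 0.906, 0.680 and 0.869 in dCA replicates 1, 2 and 3), and the quasi-likelihood test (glmQLFit and glmQLFTest) was run on all 9 libraries in one fit with 1 mean per strain and no replicate block. All tests are two-sided unless stated. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison and an absolute log2 fold change of 1 or more. A strain stood apart in a gene that was called in the same direction against both other strains. This part has no unmutated control, and shared libraries make the 2 calls dependent, so the overlap was also computed on simulated data without change.

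There were 21 gene lists, fixed before the data were examined as search words on the descriptions and KEGG entries, and 18 with at least 5 tested members were tested. The lists cover amylases, beta-glucosidases, cellulases, hemicellulases, pectinases, cytosolic and mitochondrial ribosomal proteins, respiration and tricarboxylic acid cycle, glycolysis, gluconeogenesis with glyoxylate and fatty acid oxidation, cell wall synthesis, DNA replication and histones, heat shock and oxidative stress, protein folding and secretion, secreted proteases, nitrogen and amino acid uptake, pigment and secondary metabolism, known regulators, and the 3 that were too short to test (asexual development, sugar transporters and iron uptake). The test was limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 18 lists, and it was repeated with an estimated correlation, with which no list was called in any comparison. Limma's fry, a rotation test of a list by itself and not against other genes, was also run. In dPoflbC against dCA its unadjusted p was 4.97e-05 for cytosolic ribosomal proteins, 0.000119 for cellulases and 1.13e-05 for hemicellulases. It was as small for lists that camera did not call, as 1.47e-05 for secreted proteases, so it does not set lists apart. The search words drew peptidases that may stay in the cell into the list of secreted proteases, called proteases in the report, and 2 polyketide and peptide synthases into known regulators. The list of cytosolic ribosomal proteins was also divided by whether the KEGG name has the eukaryotic e suffix (75 and 28 genes). The 28 without it may include mitochondrial ribosomal proteins. Tests were also made of 160 Gene Ontology terms of 10 to 500 members. Both the division and these terms were added after the data were seen.

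Named genes followed a rule fixed before the data were examined: per comparison the deleted genes where the annotation names them, the 6 highest and 6 lowest called genes with informative annotation, 10 RPKM or more and no overlap between libraries, up to 3 members per called list, the 8 cellulases with the highest level, up to 8 known regulators, and for each strain the 4 highest and 4 lowest genes in which it stood apart. The annotation names no gene flbC or clrC and the labels do not explain CA, so the first part of the rule named none. Genes added after their values were seen are said to be so.

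The pipeline was tested on simulated data with the dispersions and scaling factors of these libraries. In each comparison 100 genes were changed 2-fold and 100 genes 4-fold, as many up as down, among 8591 to 8609 genes. Of genes changed 4-fold the pipeline recovered 95%, 98% and 95% in the 3 comparisons. Of genes changed 2-fold it recovered 39%, 44% and 40% (75%, 73% and 81% by adjusted p alone), with 2, 4 and 3 false calls. Many more genes were called in the data, and not in equal number up and down, so these values do not test the scaling. In 20 simulated sets without change, 3 genes or fewer were called in a comparison.

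The alternatives were limma on log2(RPKM + 1) for genes at 1 RPKM or more, the same with pseudocounts of 0.1 and 5 or after quantile normalization, no filter on low counts, a filter at 5 RPKM, scaling to equal medians, no scaling beyond library size, no abundance trend in the spread, a replicate block, only the 6 libraries of a comparison, no minimum fold change, an estimated inter-gene correlation, DESeq2 with its size factors, and each library left out in turn. Other splits of the libraries were also tested. The counts and the values of named genes without dCA replicate 2 were given as an alternative added after the data were seen. Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.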

Results

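RNA sequencing measured transcript levels in 9 cultures of Penicillium oxalicum, a filamentous fungus that secretes enzymes which break down plant cell walls. The cultures belonged to 3 strains with 3 biological replicates each, labelled as deletions of PoflbC, of PoClrC and of CA and called here dPoflbC, dPoClrC and dCA. Every culture had been moved from 2% glucose (22 h) to medium without carbon (2 h) and then to 2% cellulose (4 h). No unmutated strain was among the samples, so each comparison set one deletion strain against another and does not say which of them had moved. The labels do not explain CA, and the annotation names no gene flbC or clrC, so the deleted genes could not be looked up by name. A library held 6.49 to 7.76 M reads (M, 1e+06) in 9786 genes, of which 8681 had enough reads to be tested. The 3 reads that a count of 0 allows came to 0.387 to 0.462 reads per M reads of a library, for counting error only. Levels are reads per kilobase of coding length per M reads (RPKM), as mean ± SD with n = 3 per strain. Log2 fold changes come from edgeR after scaling of the libraries and so differ from ratios of RPKM means. A gene is said to have risen or fallen where its adjusted p was under 0.05 and its log2 fold change was 1 or more in size. In each such gene named here, unless stated otherwise, the 3 libraries of one strain all lay above the 3 of the other. Genes are named by a rule fixed before the data were examined, and those chosen after their values were seen are marked as such. Each named gene whose call ended with no scaling also lost it with limma on RPKM at each pseudocount, and BGL1 in dPoflbC, ClrB, PDE_00878, PDE_02905 and PDE_09023 also after quantile normalization. Positions and the genome build are not given in the sources used here.

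The libraries grouped by strain. The first principal component (63.8% of the variance) parted dPoflbC from the other strains, and the second (27.3%) parted dPoClrC from dCA. The library of dCA replicate 2 stood apart from its group, at 59.5 on the second component against 18.1 and 26.2 for dCA replicates 1 and 3. Its 10 highest genes held 15.7% of its reads, compared with 9.90% and 11.2% in the other dCA libraries, 7.75% to 9.8% in dPoClrC and 5.53% to 6.13% in dPoflbC. The cytosolic ribosomal protein genes had a median of 49.6 RPKM in dCA replicate 2, of 179 and 127 RPKM in dCA replicates 1 and 3, of 371 to 494 RPKM in dPoClrC and of 875 to 936 RPKM in dPoflbC.

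**Figure D1:**
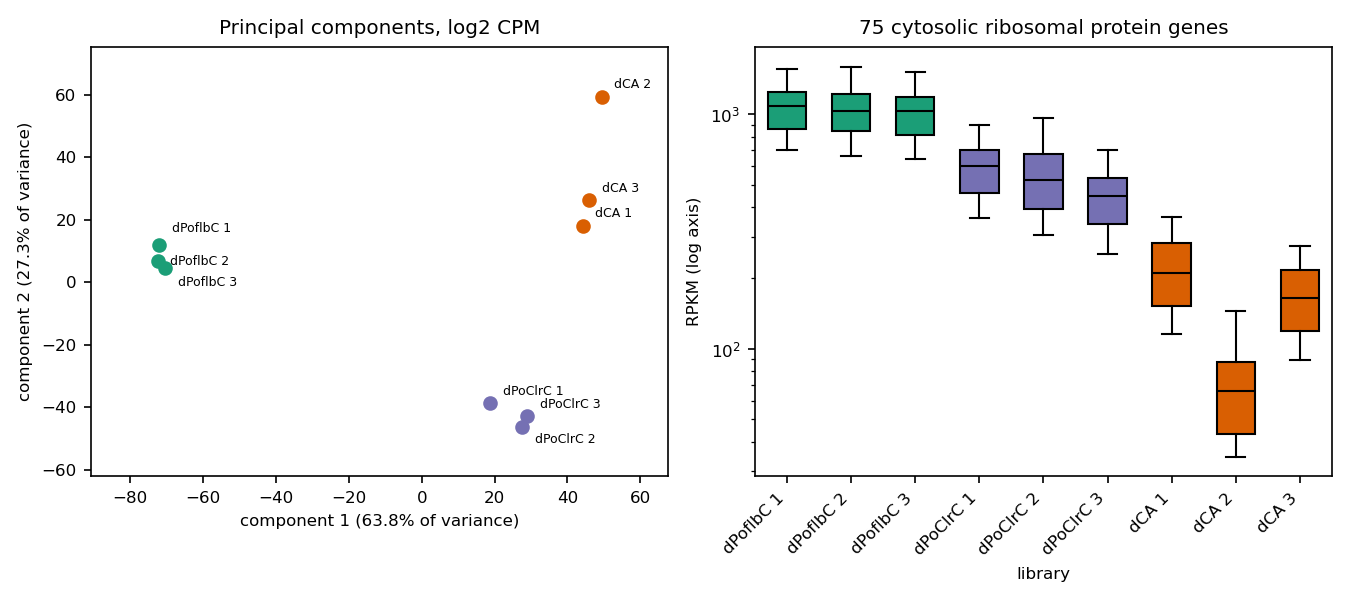
Left, the 9 libraries on the first 2 principal components of log2 counts per M reads, coloured by strain; right, RPKM (log axis) of the 75 tested cytosolic ribosomal protein genes with eukaryotic-type names in each library, with boxes at the quartiles, a line at the median and whiskers from the 10th to the 90th percentile. The boxes of dPoflbC lie highest, those of dCA lowest, and dCA replicate 2 lies below dCA replicates 1 and 3.

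The comparison of dPoflbC with dCA asks which transcripts differed on cellulose between these strains. In dPoflbC 12 of 16 cellulases and 46 of 74 hemicellulases fell and 85 of 103 cytosolic ribosomal proteins rose, though as lists their calls were lost with an estimated correlation (adjusted p = 0.433, 0.342 and 0.433). Of the ribosomal genes that rose, 73 had eukaryotic-type names and 12 had other names, which may include mitochondrial ones. The xylanase PDE_04478, which cleaves the backbone of xylan, was at 102 ± 7.81 RPKM in dPoflbC and at 18680 ± 3455 RPKM in dCA. The glucoamylase Amy15A (PDE_09417), which releases glucose from starch, was at 6.74 ± 2.00 RPKM in dPoflbC and at 3116 ± 525 RPKM in dCA. The developmental regulator BrlA (PDE_00087), a zinc finger protein that starts spore formation, was at 75.1 ± 6.31 RPKM in dPoflbC and at 3.66 ± 1.97 RPKM in dCA. Of the 8681 genes, 988 rose and 1368 fell in dPoflbC against dCA. Over all genes tested, called or not, 5918 (68.2%) had scaled levels that did not overlap between the strains, where chance gives 10%. With no scaling beyond library size, 2272 rose and 757 fell, and the median of all genes lay at 0.51 in place of -0.07 (log2), so changes are relative to the scaling. Without dCA replicate 2, 2074 of the 2356 genes were still called and 0 had reversed.

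Cellulases cleave cellulose. Of the 16 measured, 12 fell in dPoflbC against dCA and 1 rose (median log2 fold change -3.95, camera adjusted p = 0.000675). The call was lost with adjusted p = 0.433 with an estimated correlation. Adjusted over the list alone, the counts of this list and of each other list, in each comparison, were the same as those adjusted over all genes tested. The endoglucanases Cel7B (PDE_07929) and Cel45A (PDE_07928), which cut within the cellulose chain, were at 66.4 ± 26.4 and 65.2 ± 18.1 RPKM in dPoflbC and at 1096 ± 196 and 1196 ± 173 RPKM in dCA. The endoglucanases Cel5A (PDE_00507), Cel5C (PDE_09969) and PDE_09226 fell, with log2 fold changes of -4.37, -4.59 and -5.04. The cellobiohydrolase Cel6A (PDE_07124), which works from the chain end, had a log2 fold change of -5.13, or -4.26 without dCA replicate 2. The cellobiohydrolase CBHI/Cel7A-2 (PDE_07945) was at 327 ± 94.6 RPKM in dPoflbC and at 1492 ± 1267 RPKM in dCA, a log2 fold change of -2.91 that became -1.68 without dCA replicate 2. The putative endoglucanase PDE_09267 was at 545 ± 66.1 against 1053 ± 183 RPKM, with a log2 fold change of -1.53 that was -0.95 and not called with no scaling. The putative cellulose monooxygenase PDE_01261, from an oxidative family of cellulose-cleaving enzymes, was at 7.97 ± 2.53 against 164 ± 27.8 RPKM. The cellulose monooxygenase Cel61A (PDE_05633) had 1 read over the dPoflbC libraries and 432 over the dCA libraries, a ratio of 448 (95% exact binomial interval 79.96 to 17730). The member that rose, the xyloglucan-specific endoglucanase PDE_02886 (1.09), was chosen after its values were seen.

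**Figure D2:**
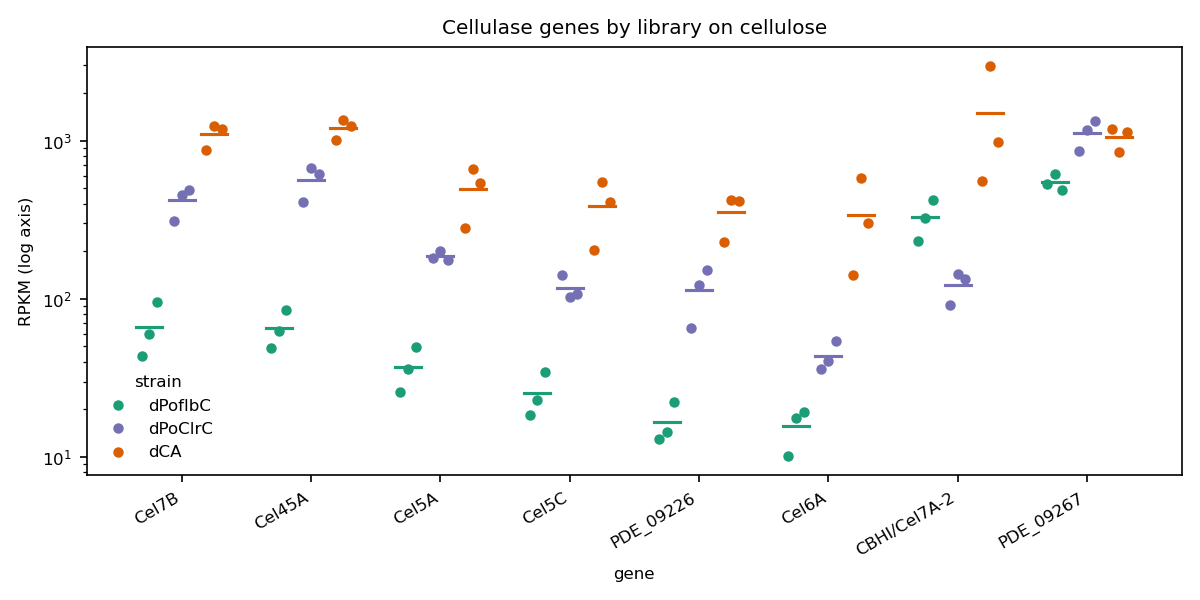
RPKM (log axis) of the 8 cellulase genes with the highest mean level, with 1 point per library, colours for the 3 strains and a bar at each strain's mean (n = 3). The points of dPoflbC lie below those of dCA in all 8 genes, and those of dPoClrC lie between in each except CBHI/Cel7A-2 and PDE_09267.

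Hemicellulases, which break down xylan and related polymers, fell in 46 of 74 genes and rose in 4 (median log2 fold change -1.55, adjusted p = 2.02e-11). This call was also lost, with adjusted p = 0.342 with an estimated correlation. The putative acetyl xylan esterase PDE_04182 was at 21.7 ± 2.49 RPKM in dPoflbC and at 4186 ± 1185 RPKM in dCA, and the putative feruloyl esterase PDE_06649 was at 22.8 ± 5.38 and 1607 ± 401 RPKM. The putative beta-xylosidase/alpha-L-arabinofuranosidase PDE_07334 and the putative alpha-1,2-L-fucosidase PDE_04858 fell, with log2 fold changes of -4.73 and -2.38. The 4 that rose, chosen after their values were seen, were PDE_02886, the putative beta-glucuronidase PDE_02801 (1.07), the putative alpha-1,6-mannanase PDE_00051 (1.02) and the putative alpha-L-arabinofuranosidase PDE_00276 (2.65, at 1.43 ± 0.0732 RPKM in dPoflbC). PDE_02801 was no longer called without dCA replicate 1 (0.995) or dCA replicate 3 (0.93), and PDE_00051 was no longer called without dCA replicate 2 (0.99) or dPoflbC replicate 3 (0.95). PDE_00276 was not called with limma on RPKM with a pseudocount of 5 (0.32) or after quantile normalization (0.78).

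Amylases and other starch-degrading enzymes fell in 8 of 13 genes and rose in 0 (median log2 fold change -1.67, adjusted p = 9.87e-07, and adjusted p = 0.342 with an estimated correlation). Beside Amy15A, the putative alpha-glucosidases PDE_04151 and PDE_00400 fell from 436 ± 146 and 953 ± 103 RPKM in dCA to 40.5 ± 1.42 and 92.5 ± 5.92 RPKM in dPoflbC. The alpha-amylase Amy13A (PDE_01201), chosen after its values were seen, was at 4.21 ± 1.45 against 564 ± 215 RPKM. PDE_01354, a protein with starch-binding and chitin-binding domains, was at 12.6 ± 0.675 against 2943 ± 581 RPKM. Beta-glucosidases, which split cellobiose to glucose, fell in 7 of 12 genes (median -1.18, adjusted p = 0.0348, and adjusted p = 0.462 with an estimated correlation). Among them PDE_04251 and PDE_02108 fell, with log2 fold changes of -2.25 and -1.29, and PDE_09710, which the gene table describes as a putative beta-xylosidase, fell by 2.78. The value of PDE_02108 was -0.71 and not called with no scaling. BGL1 (PDE_02736), chosen after its values were seen, had a log2 fold change of -1.35 that was -0.88 without dCA replicate 2 and -0.70 with no scaling, neither of them called. Pectinases, which break down pectin, fell in 11 of 23 genes (median -0.85, adjusted p = 0.0348, and adjusted p = 0.462 with an estimated correlation). The putative alpha-L-rhamnosidase PDE_06451, the putative pectate lyase PDE_06068 and the putative unsaturated rhamnogalacturonyl hydrolase PDE_01286 fell, with log2 fold changes of -4.05, -3.17 and -2.86. The 1 pectinase that rose, the putative rhamnogalacturonan alpha-L-rhamnopyranohydrolase PDE_09285 (1.95), was chosen after its values were seen. The call of the beta-glucosidases was kept without dPoflbC replicate 2 and lost without each of the other 8 libraries (adjusted p up to 0.0875, without dCA replicate 2) and with no filter on low counts (0.0525). That of the pectinases was lost without dPoflbC replicate 1, dCA replicate 1 or dCA replicate 2, with no filter on low counts (0.0506) and with DESeq2 (0.0841, the highest over the settings tried apart from the estimated correlation). With no scaling 4 members of each list fell.

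Cytosolic ribosomal protein genes, which encode the parts of the ribosome, rose in 85 of 103 members and fell in 0 (median log2 fold change 2.24, adjusted p = 1.48e-26). The call was lost with adjusted p = 0.433 with an estimated correlation. Of the 75 members with eukaryotic-type names 73 rose (median 2.33), and of the 28 with other names 12 rose (median 0.85). L39e (PDE_02248) was at 1228 ± 41.7 RPKM in dPoflbC and at 276 ± 88.6 RPKM in dCA. L7/L12 (PDE_02446) and L1 (PDE_09511), whose names lack the e suffix and are used for bacterial and mitochondrial ribosomes, had log2 fold changes of 1.27 and 1.1. The 28 genes with other names may include mitochondrial ribosomal proteins, so counts of this list need not be of cytosolic ones alone. Their median of 0.85 lay nearer that of the list of mitochondrial ribosomal proteins (0.92) than that of the 75 (2.33). Without dCA replicate 2, the library with the lowest ribosomal protein levels, 79 cytosolic ribosomal proteins rose and the median was 1.98. Mitochondrial ribosomal proteins rose in 6 of 15 genes (median 0.92, adjusted p = 5.85e-05, and adjusted p = 0.342 with an estimated correlation). Among them were L46 (PDE_07841, 1.53), L47 (PDE_03085, 1.23) and S23 (PDE_03648, 1.2). Respiration and tricarboxylic acid cycle genes rose in 5 of 80 members and fell in 1 (median 0.30, adjusted p = 0.000937, and adjusted p = 0.462 with an estimated correlation). The 5 were malic enzyme PDE_04142 (1034 ± 208 against 98.7 ± 35.5 RPKM), the succinate dehydrogenase cytochrome subunit PDE_09828 (220.5 ± 18.4 against 31.4 ± 3.52 RPKM), the cytochrome oxidase assembly protein PDE_08885 (1.38), citrate synthase PDE_09135 (1.36) and a succinyl-CoA synthetase subunit PDE_01111 (2.57). The 1 that fell was 3-isopropylmalate dehydrogenase PDE_08096 (-1.47, and -0.91 and not called with no scaling), an enzyme of leucine synthesis. PDE_09135, PDE_01111 and PDE_08096 were chosen after their values were seen. With no scaling, 31 genes of respiration and tricarboxylic acid cycle and 12 mitochondrial ribosomal proteins rose.

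The cellulase regulators XlnR and ClrB were lower in dPoflbC, and BrlA and FlbD were higher. XlnR (PDE_07674), an activator of xylanase and cellulase genes, was at 19.5 ± 1.06 RPKM in dPoflbC and at 38.8 ± 5.04 RPKM in dCA (log2 fold change -1.58, adjusted p = 3.55e-06); with no scaling the change was -0.99 and not called. ClrB (PDE_05999), an activator of cellulase genes, had a log2 fold change of -1.1 (adjusted p = 0.000315), which was not called without dCA replicate 2 (-0.89), without dPoflbC replicate 1 (-0.997) or with no scaling (-0.50). BrlA rose with a log2 fold change of 3.81 (adjusted p = 8.73e-07), and FlbD (PDE_03008), a Myb-like regulator of spore formation, was at 218 ± 9.51 against 53.1 ± 4.05 RPKM. The catabolite repressor CreA (PDE_03168) was at 243 ± 17.0 against 213 ± 21 RPKM (log2 fold change after scaling -0.40, adjusted p = 0.0195). HAC1 (PDE_01436), a regulator of the unfolded protein response, was at 285 ± 45.8 against 239 ± 34.4 RPKM (-0.33, adjusted p = 0.0872). Neither was called, and after scaling both lay below 0, against the direction of their RPKM means. The kinase PDE_02007 and the synthase PDE_04017, a polyketide and peptide synthase that the search words had drawn into the list of regulators, were not called either (31.1 ± 1.34 against 21.5 ± 4.01 RPKM, and 2.80 ± 0.0833 against 2.10 ± 0.380 RPKM). After scaling their log2 fold changes were -0.0419 and -0.16, also against the direction of their RPKM means. The cellodextrin transporters CdtC (PDE_00607) and CdtD (PDE_00753), which carry short cellulose fragments into the cell, fell, with log2 fold changes of -1.67 and -2.19, in a list too short to test. The high-affinity iron transporter PDE_07611, also in a list too short to test, fell by 2.47.

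Among the other genes with the largest changes, methylisocitrate lyase PDE_06062, an enzyme of propionate breakdown, was at 36.9 ± 14.3 RPKM in dPoflbC and at 23830 ± 9401 RPKM in dCA. The glyceraldehyde 3-phosphate dehydrogenase PDE_04588, an enzyme of glycolysis, was at 1661 ± 140.5 against 34.1 ± 14.2 RPKM. Also higher in dPoflbC were the 4-hydroxyphenylpyruvate dioxygenase PDE_08904 (191 ± 107 against 4.26 ± 1.16 RPKM), the p38 MAP kinase PDE_05603 (38.0 ± 17.8 against 0.862 ± 0.140 RPKM), the sodium-exporting ATPase PDE_03497 (82.9 ± 22.0 against 2.06 ± 0.262 RPKM) and the ribosomal RNA processing protein PDE_01999 (37.5 ± 3.73 against 1.28 ± 0.803 RPKM). For 10 lists no call was made. These were cell wall synthesis (70 of 89 genes not called, adjusted p = 0.71), DNA replication (34 of 37, 0.945), gluconeogenesis and fatty acid oxidation (20 of 29, 0.233), glycolysis (17 of 20, 0.473), heat shock (23 of 34, 0.646), known regulators (5 of 8, 0.945), nitrogen uptake (19 of 29, 0.558), pigment and secondary metabolism (6 of 14, 0.473), protein folding (30 of 31, 0.291) and proteases (22 of 29, 0.187). The median and mean of nitrogen uptake and of known regulators differed in sign.

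**Figure D3:**
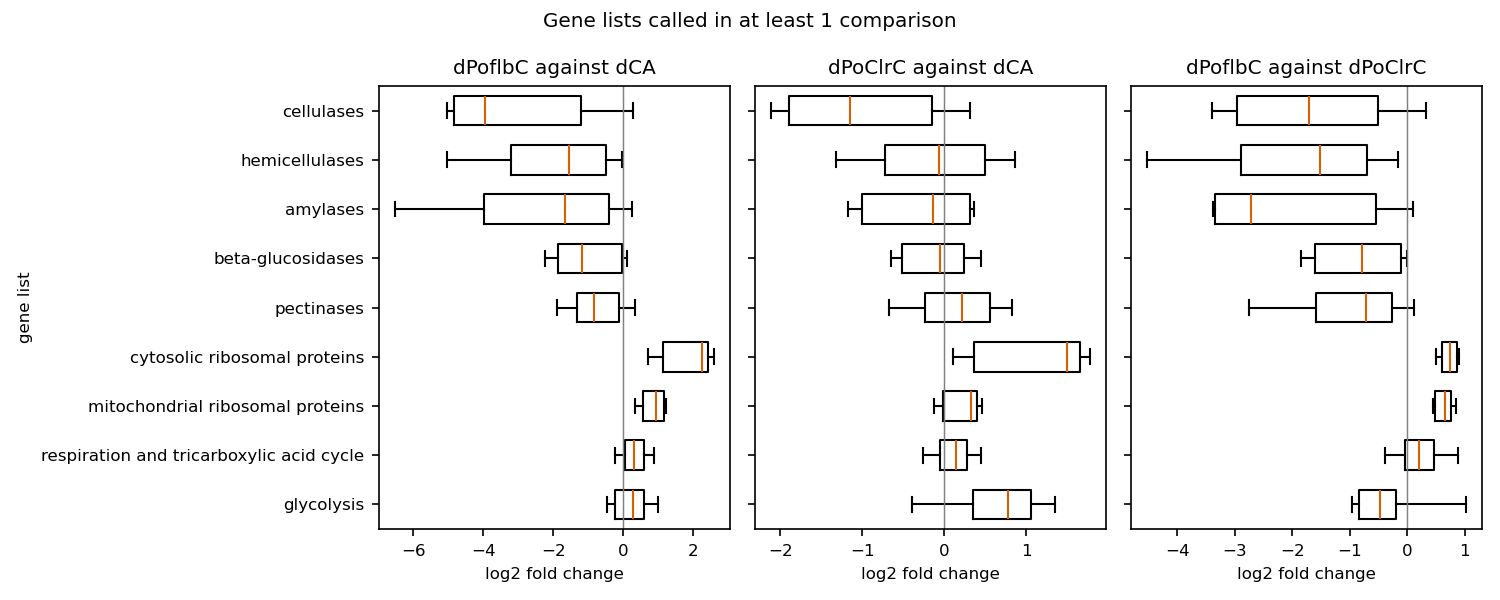
Log2 fold changes of the tested members of 9 gene lists in the 3 comparisons, with boxes at the quartiles, a line at the median and whiskers from the 10th to the 90th percentile. The medians of the cellulases, hemicellulases, amylases, beta-glucosidases and pectinases lie below 0 in dPoflbC against either other strain, and those of the cytosolic ribosomal proteins lie above 0 in all 3 panels, at 2.24, 1.5 and 0.74.

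The comparison of dPoClrC with dCA asks which transcripts differed on cellulose between the strain without PoClrC and dCA. In dPoClrC 68 of 103 cytosolic ribosomal proteins and 5 of 20 glycolysis genes rose, 1 glycolysis gene fell and 8 of 16 cellulases fell. As lists all 3 calls were lost with an estimated correlation (adjusted p = 0.959 for each). That value was the same for every list tested in this comparison, since the adjustment can give unlike p-values 1 shared adjusted value. It therefore does not say how the called lists compared with the others under this setting. The ribosomal proteins S3e (PDE_02754) and L28e (PDE_01007) were at 293 ± 42.9 and 279.5 ± 42.9 RPKM in dPoClrC and at 69.4 ± 36.8 and 66.2 ± 34.9 RPKM in dCA. Cel7B was at 418 ± 94.6 RPKM in dPoClrC and at 1096 ± 196 RPKM in dCA. In dPoClrC 494 genes rose and 638 fell. Over all genes tested, 4396 (50.6%) had scaled levels that did not overlap, where chance gives 10%. With no scaling beyond library size, 887 rose and 454 fell, and the median of all genes lay at 0.30. Without dCA replicate 2, 881 of the 1132 genes were still called and 0 had reversed.

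Of the 16 cellulases 8 fell and 0 rose in dPoClrC against dCA (median log2 fold change -1.15, adjusted p = 0.048, and adjusted p = 0.959 with an estimated correlation). Cel45A was at 563 ± 138 against 1196 ± 173 RPKM, Cel5A at 186 ± 13.2 against 493 ± 195 RPKM and Cel5C at 117 ± 21 against 388 ± 174 RPKM. PDE_09226 had a log2 fold change of -2.0. Cel6A and CBHI/Cel7A-2 had log2 fold changes of -3.39 and -4.05, which were -2.53 and -2.83 without dCA replicate 2. PDE_09267 was not called (1117 ± 237 against 1053 ± 183 RPKM, log2 fold change after scaling -0.21, adjusted p = 0.397). The call of the list was lost without dPoClrC replicate 1, dPoClrC replicate 2 or dCA replicate 3, and for genes at 5 RPKM or more (adjusted p up to 0.221 over the settings tried apart from the estimated correlation). BGL1, chosen after its values were seen, had a log2 fold change of -1.21 that was -0.74 without dCA replicate 2 and -0.84 with no scaling, neither of them called. Amy13A, also chosen after its values were seen, was at 31.4 ± 5.88 against 564 ± 215 RPKM.

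Cytosolic ribosomal proteins rose in 68 of 103 genes and fell in 0 (median log2 fold change 1.5, adjusted p = 3.08e-22, and adjusted p = 0.959 with an estimated correlation). All 68 had eukaryotic-type names (median 1.59 over 75 genes), and the 28 genes with other names had a median of 0.18. L39e was at 735 ± 92.9 against 276 ± 88.6 RPKM. Without dCA replicate 2, 64 cytosolic ribosomal proteins rose and the median was 1.20. Glycolysis genes rose in 5 of 20 members and fell in 1 (median 0.77, adjusted p = 0.0017, and adjusted p = 0.959 with an estimated correlation). The 5 were PDE_04588 (419 ± 257 against 34.1 ± 14.2 RPKM), phosphoglycerate kinase PDE_07158 (671 ± 89.8 against 238 ± 82.1 RPKM), the hexokinase PDE_03526 (1.69), enolase PDE_02546 (1.35) and fructose-bisphosphate aldolase PDE_04802 (3749 ± 951 against 1269 ± 278 RPKM). Another hexokinase, PDE_00878, fell (-1.03), but was not called without dCA replicate 2 (-0.70) or with no scaling (-0.68), with equal medians (-0.99) or with DESeq2 (-0.997). PDE_02546, PDE_04802 and PDE_00878 were chosen after their values were seen. The value of PDE_04588 was 3.34 (log2), or 2.74 without dPoClrC replicate 1. Without dCA replicate 1, 9 glycolysis genes rose, and with no scaling 11 rose.

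Among the highest rises was PDE_00008, whose orthologue entry reads 3-dehydroquinate synthase. It was at 2000 ± 395 RPKM in dPoClrC and at 136 ± 111 RPKM in dCA (log2 fold change 3.69, or 4.34 without dCA replicate 1). The siderophore transporter PDE_04184, which takes up chelated iron, was at 157 ± 20.7 against 13.3 ± 6.84 RPKM, and the nitrite reductase PDE_00370 at 11.3 ± 3.60 against 0.978 ± 0.434 RPKM. The salicylate synthetase PDE_03182 had a log2 fold change of 2.71, which was 3.29 without dCA replicate 1 and 2.12 and not called without dPoClrC replicate 2 (adjusted p = 0.0534). The lowest values in dPoClrC belonged to genes that were high in dCA, several of them most of all in dCA replicate 2. The glutathione S-transferase PDE_01194 was at 5.09 ± 0.963 RPKM in dPoClrC and at 18080 ± 27680 RPKM in dCA, and its log2 fold change of -12.33 became -8.86 without dCA replicate 2. The 4-nitrophenyl phosphatase PDE_01189 went from -10.94 to -7.87 without that library, the hydroxyphenylacetate hydroxylase PDE_04228 from -5.88 to -3.89, and the chitosanase PDE_08733 from -6.87 to -2.54. PDE_08733 was not called without dPoClrC replicate 2 (adjusted p = 0.0545) or with a pseudocount of 5 (adjusted p = 0.0771). The cytochrome P450 PDE_09199 and the aspyridone enoyl reductase PDE_09201, from the annotation of a polyketide pathway, were at 0.402 ± 0.0509 and 0.497 ± 0.2 RPKM in dPoClrC and at 45.3 ± 23.9 and 23.6 ± 11.1 RPKM in dCA. BrlA rose from 3.66 ± 1.97 to 13.3 ± 2.22 RPKM. XlnR (35.0 ± 3.93 against 38.8 ± 5.04 RPKM), ClrB (83.3 ± 7.51 against 99.0 ± 7.17 RPKM), CreA (212 ± 31.1 against 213 ± 21 RPKM), HAC1 (279 ± 19.7 against 239 ± 34.4 RPKM), PDE_02007 and PDE_04017 were not called. After scaling HAC1 had a log2 fold change of -0.09, against the direction of its RPKM means.

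For 15 lists no call was made in dPoClrC against dCA. Hemicellulases had 58 of 74 genes not called (adjusted p = 0.877), amylases 8 of 13 (0.306), beta-glucosidases 11 of 12 (0.946), pectinases 18 of 23 (0.672), mitochondrial ribosomal proteins 15 of 15 (0.27) and respiration and tricarboxylic acid cycle genes 78 of 80 (0.178). The others were cell wall synthesis (78 of 89, 0.839), DNA replication (37 of 37, 0.877), gluconeogenesis and fatty acid oxidation (23 of 29, 0.877), heat shock (30 of 34, 0.901), known regulators (7 of 8, 0.946), nitrogen uptake (24 of 29, 0.877), pigment and secondary metabolism (8 of 14, 0.27), protein folding (31 of 31, 0.877) and proteases (24 of 29, 0.877). Median, mean or test differed in sign for beta-glucosidases, heat shock, cell wall synthesis, nitrogen uptake, protein folding, known regulators and proteases.

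The comparison of dPoflbC with dPoClrC asks how the strains without PoflbC and without PoClrC differed on cellulose. In dPoflbC 48 of 74 hemicellulases, 7 of 13 amylases, 10 of 23 pectinases and 9 of 16 cellulases fell, and 2 hemicellulases and 1 pectinase rose. As lists their calls were all lost with an estimated correlation (adjusted p = 0.357, 0.298, 0.417 and 0.585). PDE_04478 was at 102 ± 7.81 RPKM in dPoflbC and at 20000 ± 9264 RPKM in dPoClrC. PDE_04182 was at 21.7 ± 2.49 against 5743 ± 3011 RPKM, and Amy15A at 6.74 ± 2.00 against 779.9 ± 84.1 RPKM. Of the genes tested, 786 rose and 1179 fell in dPoflbC. Over all genes tested, 6046 (69.6%) had scaled levels that did not overlap, where chance gives 10%. With no scaling beyond library size, 1289 rose and 876 fell, and the median of all genes lay at 0.29.

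Hemicellulases fell in 48 of 74 genes and rose in 2 (median log2 fold change -1.52, adjusted p = 3.85e-13, and adjusted p = 0.357 with an estimated correlation). PDE_06649 was at 22.8 ± 5.38 against 1746 ± 484 RPKM, and PDE_07334 and PDE_04858 fell, with log2 fold changes of -4.55 and -1.91. The 2 that rose, PDE_02801 (1.09) and PDE_00276 (1.72), were chosen after their values were seen, and without dCA replicate 2, 4 hemicellulases rose. PDE_00276 was not called with limma on RPKM at pseudocounts of 1 and 5 (0.85 and 0.26) or after quantile normalization (0.70). Amylases fell in 7 of 13 genes and rose in 0 (median -2.72, adjusted p = 3.51e-07, and adjusted p = 0.298 with an estimated correlation). PDE_00400 and PDE_04151 fell, with log2 fold changes of -3.38 and -3.35, and Amy13A, chosen after its values were seen, had -3.17. Pectinases fell in 10 of 23 genes and rose in 1 (median -0.72, adjusted p = 0.00285, and adjusted p = 0.417 with an estimated correlation). PDE_06068 was at 16.8 ± 1.81 against 206 ± 42.6 RPKM, and PDE_01286 and the putative exopolygalacturonase PDE_06891 fell, with log2 fold changes of -3.20 and -3.06. The pectinase that rose, PDE_09285 (1.87), was chosen after its values were seen.

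Cellulases fell in 9 of 16 genes and rose in 0 in dPoflbC against dPoClrC (median log2 fold change -1.71, adjusted p = 0.0132, and adjusted p = 0.585 with an estimated correlation). Cel7B and Cel45A fell from 418 ± 94.6 and 563 ± 138 RPKM in dPoClrC to 66.4 ± 26.4 and 65.2 ± 18.1 RPKM in dPoflbC. PDE_01261, PDE_09226, Cel5A, Cel5C and PDE_09267 had log2 fold changes of -4.06, -3.05, -2.60, -2.48 and -1.32. Cel61A had 1 read over the dPoflbC libraries and 453 over the dPoClrC libraries, a ratio of 485 (95% exact binomial interval 86.7 to 19210). Cel6A fell by 1.74 on the log2 scale (adjusted p = 0.017), but was not called without dPoflbC replicate 1 (adjusted p = 0.066) or dPoClrC replicate 3 (adjusted p = 0.0554). CBHI/Cel7A-2 was at 327 ± 94.6 RPKM in dPoflbC and at 122 ± 27.6 RPKM in dPoClrC (log2 fold change 1.14) and was not called with all 9 libraries (adjusted p = 0.123). It was called as higher without dCA replicate 1 (adjusted p = 0.0462), without dCA replicate 2 (0.00464), with no scaling (0.0306), with only the 6 libraries compared (0.00239) and with limma. Beta-glucosidases fell in 5 of 12 genes and rose in 0 (median -0.78, adjusted p = 0.0132, and adjusted p = 0.555 with an estimated correlation). They were PDE_09710 (-2.72), PDE_04859 (-1.92), PDE_04251 (-1.84), BGL2 (PDE_00579, -1.52) and PDE_02905 (-1.05), the last of which was -0.95 and not called without dPoflbC replicate 1 and -0.77 and not called with no scaling. BGL2 and PDE_02905 were chosen after their values were seen. The call of the list was lost without dPoClrC replicate 3 (adjusted p = 0.053).

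The cytosolic ribosomal proteins had a median log2 fold change of 0.74, and 5 of 103 rose (adjusted p = 1.79e-07, and adjusted p = 0.585 with an estimated correlation). These were L24e (PDE_05375, 1.40), L7Ae (PDE_08174, 1.09), L17e (PDE_00304, 1.09), L34e (PDE_05253, 1.08) and L5 (PDE_09351, 1.05). L5 has a name without the eukaryotic e suffix and may be a mitochondrial ribosomal protein. L17e and L34e were chosen after their values were seen. L17e was not called without dPoClrC replicate 2 (1.02, adjusted p = 0.0643) or dPoClrC replicate 3 (0.99, adjusted p = 0.0673), L7Ae not without dPoClrC replicate 3 (0.97) and L5 not without dPoClrC replicate 2 (0.98). The number of cytosolic ribosomal proteins that rose was 11 without dPoClrC replicate 1, 3 without dPoClrC replicate 2 or 3, and 55 with no scaling. Mitochondrial ribosomal proteins had a median of 0.65 (adjusted p = 0.00126, and adjusted p = 0.417 with an estimated correlation). S23 (PDE_03648) was the 1 of 15 that rose (1.03), 0 rose without dPoClrC replicate 2 (S23 at 0.997), and 4 rose with no scaling. Respiration and tricarboxylic acid cycle genes rose in 5 of 80 members and fell in 1 (median 0.20, adjusted p = 0.0245, and adjusted p = 0.585 with an estimated correlation). The 5 were PDE_04142 (2.69), PDE_01111 (2.05), PDE_09828 (2.0), the complex I assembly factor PDE_08330 (1.16) and PDE_07494 (1.08), which is annotated as a cytochrome c oxidase assembly factor and as a mannosyltransferase. The 1 that fell was PDE_08096 (-1.66). PDE_08330, PDE_07494 and PDE_08096 were chosen after their values were seen, and PDE_07494 was not called without dPoClrC replicate 1 (0.91) or dPoflbC replicate 1 (0.84), with limma at a pseudocount of 5 (0.95) or after quantile normalization (0.997). The list was not called without dPoClrC replicate 3 (adjusted p = 0.053), and 11 of its genes rose with no scaling.

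The regulator XlnR fell from 35.0 ± 3.93 to 19.5 ± 1.06 RPKM (log2 fold change -1.12, adjusted p = 4.24e-05), and with no scaling the change was -0.85 and not called. BrlA and FlbD rose from 13.3 ± 2.22 and 49.9 ± 4.87 RPKM in dPoClrC to 75.1 ± 6.31 and 218 ± 9.51 RPKM in dPoflbC. ClrB (70.1 ± 10.2 against 83.3 ± 7.51 RPKM), CreA, HAC1, PDE_02007 and PDE_04017 were not called. CdtC and CdtD fell, with log2 fold changes of -1.41 and -2.04. The iron transporters PDE_07611 and PDE_04184 fell, with log2 fold changes of -3.01 and -3.30. The gene PDE_00008 was at 7.06 ± 0.510 against 2000 ± 395 RPKM, and its neighbour in locus number, the catechol O-methyltransferase PDE_00009, at 0.843 ± 0.127 against 777 ± 67.7 RPKM. Among the highest rises were the branched-chain amino acid aminotransferase PDE_03805 (164 ± 39.7 against 6.33 ± 0.913 RPKM), PDE_08904 (191 ± 107 against 1.65 ± 0.502 RPKM) and the indoleamine dioxygenase PDE_05907 (317 ± 106 against 9.97 ± 4.17 RPKM), an enzyme of tryptophan breakdown. PDE_01194 and PDE_01189 rose by 8.06 and 5.56 on the log2 scale, and the L-lactate dehydrogenase PDE_01482 by 3.99, or 4.78 without dPoClrC replicate 1. For 10 lists no call was made. These were cell wall synthesis (73 of 89 genes not called, adjusted p = 0.981), DNA replication (36 of 37, 0.814), gluconeogenesis and fatty acid oxidation (22 of 29, 0.223), glycolysis (15 of 20, 0.223), heat shock (23 of 34, 0.476), known regulators (6 of 8, 0.972), nitrogen uptake (17 of 29, 0.355), pigment and secondary metabolism (9 of 14, 0.0777), protein folding (31 of 31, 0.153) and proteases (20 of 29, 0.0599). The median and mean of heat shock differed in sign.

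Genes that differed in one strain from both others, in the same direction, are given here by that strain. Without an unmutated strain they do not say which of the strains had moved. A gene can also be given for more than 1 strain, as PDE_00009 was for dPoflbC and dPoClrC. The strain dPoflbC stood apart most, with 491 genes higher and 819 lower than in both other strains. Polysaccharide-degrading enzymes made up part of the lower genes, with 40 of 74 hemicellulases, 9 of 16 cellulases, 7 of 13 amylases and 9 of 23 pectinases. On the other side, 2 hemicellulases and 1 pectinase were higher than in both other strains. PDE_04182, PDE_04478, PDE_00009 and Cel61A were among the lower genes and PDE_08904, PDE_01482, PDE_05603 and PDE_03497 among the higher. The strain dPoClrC had 192 genes higher and 179 lower. PDE_00008, PDE_00009, PDE_04184 and PDE_03182 were among the higher, and PDE_01194, PDE_01189, PDE_05907 and the maleylacetoacetate isomerase PDE_08908 among the lower. PDE_03182 is called in dPoClrC against dCA with all libraries and not without dPoClrC replicate 2, and its log2 fold change in dPoflbC against dPoClrC went from -4.91 to -6.06 without dPoflbC replicate 1 and to -4.31 without dPoClrC replicate 2. The values of PDE_05907 and PDE_08908 in dPoClrC against dCA (-4.35 and -4.90) were -2.64 and -3.54 without dCA replicate 2. The strain dCA had 404 genes higher and 251 lower. Of the cytosolic ribosomal proteins 68 of 103 were lower in dCA than in both other strains, and 8 of 16 cellulases and 12 of 74 hemicellulases were higher. Of the hemicellulases 1 was lower. PDE_09199, PDE_09201, PDE_01189 and the salicylate hydroxylase PDE_07956 were among the higher and PDE_04588, the monooxygenase PDE_09999 and the fatty acid desaturase PDE_06752 among the lower. PDE_07956 had log2 fold changes of -5.65 in dPoflbC and -5.57 in dPoClrC against dCA, which were -3.76 and -3.69 without dCA replicate 2. PDE_06752 had a log2 fold change of 2.22 in dPoClrC against dCA, which was 0.69 and not called with limma on RPKM with a pseudocount of 5, so that it no longer stood apart there. PDE_09999 had log2 fold changes of 2.67 and 2.64, which were 3.29 and 3.26 without dCA replicate 1. PDE_01189 had a log2 fold change of -5.38 in dPoflbC against dCA, which was -2.30 without dCA replicate 2. PDE_01482 had a log2 fold change of 3.96 in dPoflbC against dCA, which was 4.63 without dCA replicate 3. Overlap at random of the calls gives 89.5 and 186 genes for dPoflbC, 67.1 and 57.8 for dPoClrC and 100.5 and 56.2 for dCA, but both comparisons share a strain's libraries. In 20 simulated sets with no difference between the strains the mean was 0.05 genes or fewer and the highest 1. At most 3 genes were called per comparison in these sets. They therefore cannot show how much overlap shared libraries give when many genes are called.

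In each strain 1 gene had 3 reads or fewer over its libraries and 50 or more in each library of the other strains; these genes were chosen after their values were seen. PDE_08372, a hypothetical protein, had 0 reads in dPoflbC, at least 249.9-fold below dPoClrC and at least 157-fold below dCA, with 3 counts over the strain as the floor. PDE_09023, a hypothetical protein, had 0 reads in dPoClrC, at least 523-fold below dPoflbC and at least 816-fold below dCA. PDE_01542, whose orthologue entry reads next to BRCA1 gene 1 protein, had 1 read in dCA and 22123 in dPoflbC, a ratio of 21340 (95% exact binomial interval 3830 to 842900). In dPoClrC it had 17274 reads, a ratio of 17850 (interval 3203 to 705000). PDE_09023 was also lower in dPoflbC (83.3 ± 15.2 RPKM) than in dCA (128 ± 29.0 RPKM), but this was not called without dCA replicate 2 (-0.88) or with no scaling (-0.62).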

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

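The settings here were chosen before the data were examined. The total counts of genes called in a comparison, and of genes in which a strain stood apart, stayed within 1.5 times their main value under most settings, and with each library left out in turn; counts within some gene lists moved by more, as given with those lists. The exceptions were settings that do not scale the libraries for composition, or that change the fold minimum. With limma on log2(RPKM + 1), 2161 genes were higher and 706 lower in dPoflbC against dCA, 779 higher and 424 lower in dPoClrC against dCA, and 1208 higher in dPoflbC against dPoClrC. With a pseudocount of 0.1 these were 2426 higher and 760 lower, 943 higher, and 1345 higher; with a pseudocount of 5 the lower genes numbered 585, 334 and 665 in the 3 comparisons. With no scaling beyond library size, 2272 were higher and 757 lower in dPoflbC against dCA, 887 higher in dPoClrC against dCA and 1289 higher in dPoflbC against dPoClrC. The median of all genes lay at 0.51, 0.30 and 0.29 in place of -0.07, 0.0017 and 0.0109 under this setting, which by its construction raises the counts of higher genes. With no minimum fold change, 2356 and 2932, 1554 and 1726, and 2395 and 2559 genes were higher and lower, and 3555, 1329 and 1855 genes stood apart in dPoflbC, dPoClrC and dCA, as the lack of a minimum brings in smaller changes. With an estimated inter-gene correlation 0, 0 and 0 lists were called in the 3 comparisons.

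Over the 9 libraries left out in turn, 956 to 1069 genes were higher and 1269 to 1437 lower in dPoflbC against dCA, 416 to 613 and 507 to 726 in dPoClrC against dCA, and 739 to 845 and 1147 to 1233 in dPoflbC against dPoClrC. The lists called numbered 6 to 8, 2 to 4 and 6 to 10. The genes that stood apart numbered 1269 to 1393 in dPoflbC, 305 to 434 in dPoClrC and 525 to 793 in dCA. With a replicate block the counts were 992 and 1340, 481 and 615, and 787 and 1179, and the replicate numbers did not pair the samples: 2 of 9 pairs of equal number had a residual correlation over 0.1 (range -0.176 to 0.12). Of the values of named genes, 3875 kept their direction and their side of an adjusted p of 0.05, 11 passed it, 45 no longer did and 60 reversed. DESeq2 gave no adjusted p for 22 genes per comparison.

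The reversed values belong to 5 genes that were not called in the comparison concerned. With no scaling the reversals follow from the setting itself, which raises all genes alike in these comparisons and so lifts values that lay under 0 by less than this shift above it. Limma on RPKM at each pseudocount does not scale for composition either. With log2(RPKM + 1) the medians of all genes lay at 0.49, 0.29 and 0.27 in the 3 comparisons, a similar shift. For the remaining settings the cause was not tested. HAC1 (PDE_01436) was at -0.33 in dPoflbC against dCA and at 0.25, 0.25 and 0.24 with limma at pseudocounts of 1, 0.1 and 5 and 0.25 with no scaling. It was at -0.09 in dPoClrC against dCA and at 0.23, 0.23, 0.22 and 0.22 in these settings. In dPoflbC against dPoClrC it was at -0.24 and at 0.0199, 0.0199, 0.0198 and 0.0308, and at 0.0166 after quantile normalization. CreA (PDE_03168) was at -0.40 in dPoflbC against dCA and at 0.19, 0.19, 0.19 and 0.19, and at -0.08 in dPoflbC against dPoClrC and at 0.20, 0.20, 0.20, 0.19 and, after quantile normalization, 0.21. PDE_04017 was at -0.16 in dPoflbC against dCA and at 0.30, 0.41, 0.14 and 0.41. PDE_09267 was at -0.21 in dPoClrC against dCA and at 0.0776, 0.0776, 0.0773 and 0.085, and at 0.0136 after quantile normalization. The kinase PDE_02007 lay near 0 in all comparisons. In dPoflbC against dCA it was at -0.0419 and at 0.53, 0.55, 0.46 and 0.53, at 0.0222 after quantile normalization, 0.0238 with equal medians, 0.004 with only 6 libraries and 0.0056 with DESeq2. In dPoClrC against dCA it was at -0.0395 and at 0.26, 0.27, 0.22 and 0.26, at 0.0225 after quantile normalization, 0.0014 with equal medians and 0.0131 without dPoClrC replicate 2 (the highest of those with 1 library left out; the lowest was -0.1157). In dPoflbC against dPoClrC it was at -0.0024 and at 0.27, 0.28, 0.24 and 0.27, at 0.0049 with no filter, 0.0225 with equal medians, 0.0075 with only 6 libraries, 0.0006 with a replicate block and 0.0173 with DESeq2. It was at 0.0131 without dPoflbC replicate 2, 0.0056 without dPoflbC replicate 3, 0.0728 without dPoClrC replicate 1 (the highest; the lowest was -0.0515, without dPoClrC replicate 2), 0.0089 without dCA replicate 2 and 0.0013 without dCA replicate 3.

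On simulated data with 3 libraries per strain, an adjusted p under 0.05 found 75%, 73% and 81% of genes changed 2-fold and 95%, 98% and 96% of genes changed 4-fold. With the fold minimum, which equals the simulated change, 39%, 44% and 40% of the former were called. Depth itself was not varied. Few genes were changed, as many up as down, so the scaling was not tested either.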

Other observations

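All tests in this part, including the Gene Ontology terms, were chosen after the results were seen. Terms of the Gene Ontology showed groups that the fixed lists had not. Of 16 genes with a cellulose-binding annotation, 15 fell in dPoflbC against dCA (median log2 fold change -4.56, adjusted p = 1.02e-08 over 160 terms), 11 fell in dPoClrC against dCA (-1.30, 0.00042) and 14 fell in dPoflbC against dPoClrC (-2.76, 3.02e-05). Of 22 genes annotated to the extracellular region, 17 fell in dPoflbC against dCA (-3.39, 9.61e-07) and 17 fell against dPoClrC (-2.04, 3.02e-05). Aspartic endopeptidases, which digest protein, fell in 7 of 11 genes in dPoflbC against dCA (-1.36, 0.00553). Ribosome biogenesis genes, which make and assemble ribosomes, rose in 9 of 11 genes in dPoflbC against dCA (1.8, 1.97e-06) and in 6 of 11 against dPoClrC (1.03, 0.00233). These calls were all lost with an estimated correlation (adjusted p = 0.663 against dCA and adjusted p = 0.824 against dPoClrC for dPoflbC, and adjusted p = 0.853 for dPoClrC against dCA), and some of the genes also belong to the cellulases and ribosomal lists.

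The library of dCA replicate 2 lay apart from dCA replicates 1 and 3. A library of another strain, or one mixed with it, was argued against by PDE_01542, which had 0 reads in dCA replicate 2 and so allows at most 0.0515% of RNA from either other strain. A few genes taking most of the counts was argued against as the whole cause. The root mean square difference (log2) to the nearer dCA library was 1.965 times that between dCA replicates 1 and 3 before scaling with all genes, and was still 1.632 times it after scaling and without the 100 highest genes of dCA replicate 2 (1.577 without the 500 highest). Across genes, which are not independent replicates, its differences to 1 of the other dCA libraries correlated with the difference of the remaining dCA library from the dPoClrC mean at r = 0.51 and 0.393 (0.134 and 0.042 for dPoflbC), so the culture may have carried the differences of dCA from dPoClrC further. A difference in growth or in time on cellulose stays open, since the labels record none.

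Of the 103 cytosolic ribosomal protein genes 68 were lower in dCA than in both other strains. A bias from coding length was argued against, as 10000 lists matched on length and level reached a median of at most 0.1926 in dPoClrC against dCA, where the ribosomal list had 1.5. A scaling factor moves all genes of a library alike, and library scaling was argued against by the median of the list, which lay 1.498 above that of all genes. As the sole source, dCA replicate 2 was argued against by the median without it, 1.1974. These values are relative to the other genes. GC content was not tested, for lack of sequence, and stays open, as do a difference between the strains and a lower growth rate of dCA cultures, for which the labels give no measure.

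In each strain 1 gene had 3 reads or fewer where every other library had 50 or more (PDE_08372 in dPoflbC, PDE_09023 in dPoClrC and PDE_01542 in dCA). Chance absence of reads was argued against, since 0 of the 81 other sets of 3 libraries had such a gene. A candidate explanation, the deleted gene of each strain, had the count it needs, with 3 of 3 strains showing exactly 1 such gene. That count depends on cutoffs set after the values were seen. Cel61A (PDE_05633) had 1 read over the dPoflbC libraries and 34 or more in each other library, so a cutoff of 34 would add it. Deletion cannot be told apart from another loss of the locus in each strain. The sources used here do not pair the names of the deleted genes with locus numbers.

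Genes in which a strain stood apart lay next to each other in locus number more often than under random placement, which may point to regulation of gene clusters. There were 300 neighbouring pairs in the same direction for dPoflbC, 70 for dPoClrC and 141 for dCA, against means of 93.2, 7.01 and 23.1 over 10000 permutations (highest 129, 19 and 42; one-sided permutation p = 1e-04 for each, the smallest these permutations can give, and 1e-04 after adjustment over the 3). Runs of 5 or more such genes numbered 7, 3 and 6. The longest were PDE_01212 to PDE_01220, 9 genes lower in dPoClrC that include both subunits of the fatty acid synthase, and PDE_00802 to PDE_00809, 8 genes higher in dPoClrC. The runs PDE_04476 to PDE_04481, with the xylanase PDE_04478, and PDE_07670 to PDE_07674, with XlnR, were lower in dPoflbC. A locus number is not a position, and whether neighbours lie side by side in the genome was not tested.

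Other splits of the libraries were tested against the real ones. Of the 10 splits of 6 libraries, 1, 1 and 1 gave as many called genes as the real one in dPoflbC against dCA (2356), dPoClrC against dCA (1132) and dPoflbC against dPoClrC (1965), and the highest of the others gave 0, 0 and 0 with edgeR. A mixed split puts the differences between strains into the spread within its groups. Few calls follow from that construction, so the values of 0 do not decide on chance. At an unadjusted p under 0.05 the other splits gave 67 to 249, 136 to 733 and 30 to 142 genes and the real ones 5631, 4160 and 5398; no other tool was run on the splits. For gene lists, 2, 10 and 5 of the 10 splits gave as many calls as the real 8, 3 and 8, and the highest of the others gave 10, 7 and 12. With 10 splits the share cannot fall under 0.05. For genes in which a strain stood apart, 4 of 100 splits of the 9 libraries gave as many as the real one for dPoflbC (1310). The highest other gave 1426. The 3 others that gave as many all kept the dPoflbC libraries together. The share therefore reflects how often a drawn split keeps these libraries together and does not decide on chance. For dCA (655) 4 splits and for dPoClrC (371) 9 splits gave as many, with the same highest other. The other splits among these, 3 and 8, all kept another strain together, so these counts do not test the grouping of dCA or dPoClrC itself. In 20 simulated sets with no difference between the strains at most 1 gene stood apart in dCA and 0 in dPoClrC, but genes vary independently in such sets, which real cultures need not do. The highest of the splits with no strain kept together gave 0 with edgeR, and no other tool was run on them. Such splits also hold the differences between strains within their groups, so this 0 does not decide on chance either.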
